A study of Mus musculus with 6 samples.

How the data were processed

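RNA from 6 mouse libraries was measured by RNA-seq: 3 of osteoblasts sorted for green fluorescent protein (GFP) from calvaria, the skull roof, and 3 of chondrocytes from rib cartilage, all from C57BL/6 mice at postnatal day 1. Osteoblasts were released with Liberase and chondrocytes with Pronase and Collagenase D, per the labels' protocols, and libraries were made with an Illumina TruSeq kit with some modifications. The osteoblasts are labelled Sp7 positive and the chondrocytes wild type. Cell type, anatomical site, sorting, genotype and digestion enzyme therefore all go with the group, and no covariate could separate them.

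The authors deposited one table of RPKM (reads scaled to transcript length and to sequencing depth). It lists 31055 RefSeq transcripts with a gene symbol and one value per library. The submitters' processing notes name TopHat2 2.0.8 and the mouse build mm9. The program that counted reads is not given in the sources used here. Every deposited RPKM value carries an added constant of 0.0001, so a transcript without reads is listed at 0.0001. How reads were divided between transcripts of one gene, and between near-identical genes, is not given in the sources used here. All 6 value columns were used, and each was matched to its sample by the name in its header.

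The table holds no read counts, but its low values move in steps. From those steps and transcript lengths in GENCODE M21, matched by RefSeq identifier, the number of reads behind each library's RPKM was estimated. Of 11580 values under 20 reads in genes with 1 transcript, 62.9% came within 0.05 of a whole number, against 10% by chance. The read totals were fitted to low values of the same genes, so part of this excess is built in. At these depths 1 RPKM in a 2 kb transcript stands for 54.1 to 71.9 reads. GENCODE M21 describes build GRCm38, not mm9, so it supplied lengths and exon make-up only, and no coordinates are given.

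The transcripts belong to 23364 gene symbols, of which 18917 have 1 transcript and 4447 have several, up to 22. The plan written before the data were examined spoke of genes and kept each line of the table as deposited. The lines turned out to be transcripts, so RPKM was summed over the transcripts of a symbol, and the analysis of single transcripts became an added alternative. Genes with RPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 11218. A gene near 0 in 1 cell type passes only if all 3 libraries of the other are high, which builds in its direction. The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), two-sided, with a variance trend and robust moderation. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are osteoblast minus chondrocyte on the log2(RPKM + 1) scale, which understates the change of genes of low RPKM. The fold values printed beside them are ratios of mean RPKM. On simulated data for these 11218 genes with 200 changed, this procedure recovered 83% of genes changed by a log2 value of 1 and 93% of those changed by 2. In that simulation 3.30% of calls were false. It changed few genes, as many up as down, all with a log2 value above 1 in chondrocytes, and shifted no whole library. Its rate therefore does not cover calls that depend on the scaling.

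Gene lists were fixed before the data were examined, from textbook knowledge: 21 lists of skeletal biology and 12 control lists of other cell types, dissociation stress, sex-linked and ribosomal protein genes. The 28 lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01. Camera is competitive: it asks whether a list lies above or below the other tested genes. It was repeated with an estimated correlation, and fry was run as a test of a list on its own. Named genes follow a rule also fixed before the data were examined. It takes Sp7 and the Dlx genes, the 5 largest changes each way among called genes whose groups do not overlap, up to 4 called members per biology list, 2 per control list, the uncalled members of highest level, and the 5 most abundant genes of each cell type, leaving out unnamed predicted genes among the largest changes. Not every gene that the rule takes is named in the text. Other genes, such as Runx2 and those that complete a count of 5 or fewer, were named after their values were seen.

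Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of mean RPKM of at least 5, 4 scalings of the libraries, moderation without trend, the replicate number as a block, library weights, each library left out, 1 transcript per gene, limma treat, and removal of the control lists. Added after seeing the data were the test of transcripts as deposited, limma voom on reads worked back from RPKM, and a test of transcript shares. The share of each transcript in its gene was computed for 1258 genes with several transcripts and RPKM of at least 5 in all libraries. Only the 3051 transcripts with a mean share above 2% over the libraries were tested. Shares under 1% were raised to 1%, and log2 odds were tested with limma. That floor was chosen while the procedure was being tried on simulated data, where floors of 1% and 0.1% and moderation with and without the robust option were run, and single simulations gave more false calls than the 5% aimed at. Over 20 simulations of 3051 transcripts, 200 of them changed by a log2 odds of 2, false calls averaged 4.51% of calls with each transcript's own residual SD and 4.93% with moderated SDs. The share recovered averaged 76.5% and 92.1%. Family medians, for families chosen after seeing the data, were set against 10000 random lists matched on transcript length and expression, and the families were tested by camera with an estimated correlation. On 40 random lists of 79 genes that procedure placed 3 unshifted lists outside its 95% range and 38 lists shifted by 0.3. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The labels do not say whether replicates came from separate mice or litters, so p-values measure only the spread between these samples, which may be technical.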

Results

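Osteoblasts, the cells that lay down bone, were compared with chondrocytes, the cells of cartilage, in newborn mice. The osteoblast group held 3 libraries of GFP-sorted, Sp7-positive calvarial cells, and the chondrocyte group held 3 libraries of wild-type rib cartilage cells. Sp7, also called Osterix, is a zinc finger transcription factor needed for bone formation, and the series title links it to the homeodomain factors of the Dlx family. The comparison asks which genes set Sp7-positive osteoblasts apart from chondrocytes. By the estimated read totals, 1 RPKM in a 2 kb transcript stood for 69.4, 67.5 and 54.1 reads in osteoblast replicates 1 to 3 and for 67.3, 67.4 and 71.9 reads in chondrocyte replicates 1 to 3. On the log2 scale the libraries correlated across tested genes, which are not independent replicates, at r of 0.992 to 0.994 within osteoblasts, 0.961 to 0.986 within chondrocytes and 0.777 to 0.820 between the groups. The first principal component held 90.4% of the variance and separated the cell types.

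Sp7 itself stood at 119 ± 13.4 RPKM in osteoblasts and 1.44 ± 0.761 RPKM in chondrocytes (SD, n = 3 each), 82.5-fold higher in the sorted cells. Its log2 difference was 5.66 ± 0.21 (SE), with an adjusted p of 1.70e-06 (limma, Benjamini-Hochberg). The osteoblasts were selected as Sp7 positive, so this difference was largely set in advance and serves as a check of the labels. Dlx5 rose from 1.06 ± 0.276 to 44.3 ± 0.397 RPKM (log2 difference 4.47), Dlx6 from 0.0440 ± 0.0538 to 15.7 ± 0.812 RPKM (358-fold), and Dlx3 from 0.0986 ± 0.114 to 9.29 ± 1.72 RPKM (3.22). All 3 Dlx genes that could be tested were higher in osteoblasts, also when adjusted over the list alone. Dlx3 and Dlx6 passed the filter through the osteoblast libraries alone. Without a filter on low values 5 of 6 were higher in osteoblasts and 0 in chondrocytes. Dlx1, Dlx2 and Dlx4 did not pass the filter, with means of 0.0211, 0.208 and 0.161 RPKM in osteoblasts. The Dlx list lay above the other tested genes (camera in limma, Benjamini-Hochberg adjusted p = 0.0168), but with adjusted p = 0.237 with an estimated correlation.

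Of 9 Sp genes, which share the zinc finger domain of Sp7, 5 were tested. Sp7 and Sp3 were higher in osteoblasts, Sp4 was higher in chondrocytes at 2.44 against 0.827 RPKM, and Sp1 and Sp2 were not called. The same counts held when adjusted over the list alone. Sp3 rested on a log2 difference of 0.27 (limma, Benjamini-Hochberg adjusted p = 0.0348). That call was lost without any of osteoblast replicates 1, 2 and 3 or chondrocyte replicate 1 (adjusted p 0.112, 0.0657, 0.101 and 0.0988), and its sign turned under median-of-ratios scaling (-0.20), where the list counted 1 higher and 3 lower. The list's median was -0.01, its mean 0.99, and camera placed it on the chondrocyte side (adjusted p = 0.486).

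**Figure D1:**
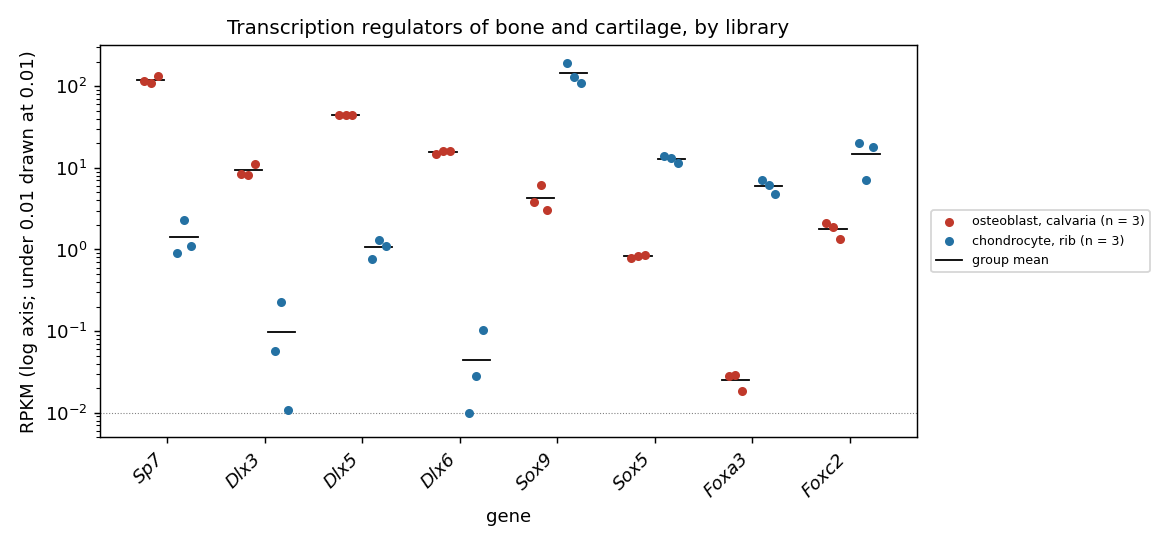
RPKM of 8 transcription regulators (log axis) in the 3 osteoblast and 3 chondrocyte libraries, one point per library, with group means as lines and values under 0.01 drawn at 0.01. Sp7, Dlx3, Dlx5 and Dlx6 lie higher in every osteoblast library, and Sox9, Sox5, Foxa3 and Foxc2 lie higher in every chondrocyte library.

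Regulators of osteoblast differentiation separated the cell types: 11 of 15 tested were higher in osteoblasts, 2 were higher in chondrocytes and 2 were not called, and the same numbers held adjusted over the list alone. Runx2, the factor that starts osteoblast commitment, was present in both cell types, at 35.8 ± 1.61 against 9.26 ± 0.167 RPKM (log2 difference 1.84), and was chosen after values were seen. Atf4 (221 ± 17.5 against 110 ± 11.8 RPKM) and Foxo1 (-0.59) were the 2 that were higher in chondrocytes. Fosl2 (27.9 against 24.5 RPKM) and Zbtb16 were not called. Camera placed the list on the osteoblast side (limma, Benjamini-Hochberg adjusted p = 0.0335), with adjusted p = 0.207 with an estimated correlation.

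Genes of bone matrix and mineralization gave the largest osteoblast differences. Ibsp, bone sialoprotein, stood at 707 ± 212 RPKM against 1.33 ± 0.454, a 532-fold difference (log2 difference 8.22 ± 0.23 SE, limma with Benjamini-Hochberg adjusted p = 6.78e-07). Dmp1, a mineral-binding protein of late osteoblasts and osteocytes, stood at 102 ± 29.0 against 0.141 ± 0.0366 RPKM (6.46). The osteocalcin genes Bglap and Bglap2 differed by 7.21 and 6.77, but they are near-identical copies and the division of reads between them is uncertain. Of 21 tested members 17 rose, 3 were lower and Enpp1 was not called, likewise adjusted over the list alone. Sparc, an abundant collagen-binding glycoprotein of bone, was among the 3 that were lower, at 5646 ± 443 against 9294 ± 1627 RPKM (-0.71), with Omd (-2.09) and Tnfrsf11b (-0.90). The type I collagen genes Col1a1 and Col1a2 were the most abundant osteoblast genes, at 19728 ± 1067 and 11397 ± 370 RPKM, yet held 4098 ± 3176 and 3649 ± 2541 RPKM in chondrocytes. Replicate 3 raised these chondrocyte means (Col1a1 2270, 2259 and 7765 RPKM, Col1a2 2388, 1985 and 6574 RPKM in replicates 1 to 3). The camera test of the list in limma gave a Benjamini-Hochberg adjusted p = 0.0212, and adjusted p = 0.188 with an estimated correlation.

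All 7 tested osteocyte markers were higher in the osteoblast libraries, also adjusted over the list alone. Without a filter on low values all 9 were. Sost, an inhibitor of Wnt signalling secreted by osteocytes, stood at 10.3 ± 3.45 RPKM against 0.00938 ± 0.00805, Irx5 at 24.5 against 0.180 RPKM and Phex at 20.6 against 0.118 RPKM. Camera in limma gave a Benjamini-Hochberg adjusted p = 0.00453 for the list, and adjusted p = 0.396 with an estimated correlation. Markers of myeloid cells (7 of 7 tested) and osteoclasts (4 of 4: Acp5, Ctsk, Itgb3 and Mmp9) were also higher in the osteoblast libraries, all of them also adjusted over the list alone. Without a filter on low values 11 of 13 myeloid and 6 of 8 osteoclast markers were higher there, and 0 were lower. Lyz2 reached 7.43 ± 1.58 RPKM and Mmp9 4.19 ± 0.947 RPKM in osteoblasts. Ctsk was at 199 ± 4.79 RPKM, against 87.9 ± 64.6 in chondrocytes, and its call (limma, Benjamini-Hochberg adjusted p = 0.0211) was lost without any one of the osteoblast libraries (adjusted p 0.0559 to 0.0584) and without chondrocyte replicates 1 (0.0697) or 2 (0.0779). These lists did not stand apart from other genes by camera (adjusted p = 0.120 and 0.122).

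Cartilage matrix genes gave the largest differences of the whole comparison. Col2a1, the main collagen of cartilage, took 9.43% to 17.7% of all RPKM in the chondrocyte libraries, at 37358 ± 10651 RPKM against 30.8 ± 6.21 in osteoblasts, 1213-fold higher (log2 difference -10.18 ± 0.24 SE, limma with Benjamini-Hochberg adjusted p = 4.08e-07). Comp, a matrix glycoprotein that binds collagen, reached 1722 ± 172 against 2.34 ± 0.376 RPKM (-9.01). Col9a2, Col9a3 and Lect1, the gene of chondromodulin, differed by -9.01, -8.87 and -8.94. Of 22 tested cartilage matrix genes 21 were higher in chondrocytes, and the same 21 calls were counted adjusted over the list alone. Matn4 was not called, at 43.2 ± 11.4 against 32.6 ± 9.85 RPKM. The camera test of the list in limma gave a Benjamini-Hochberg adjusted p = 5.24e-28, and adjusted p = 0.166 with an estimated correlation.

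**Figure D2:**
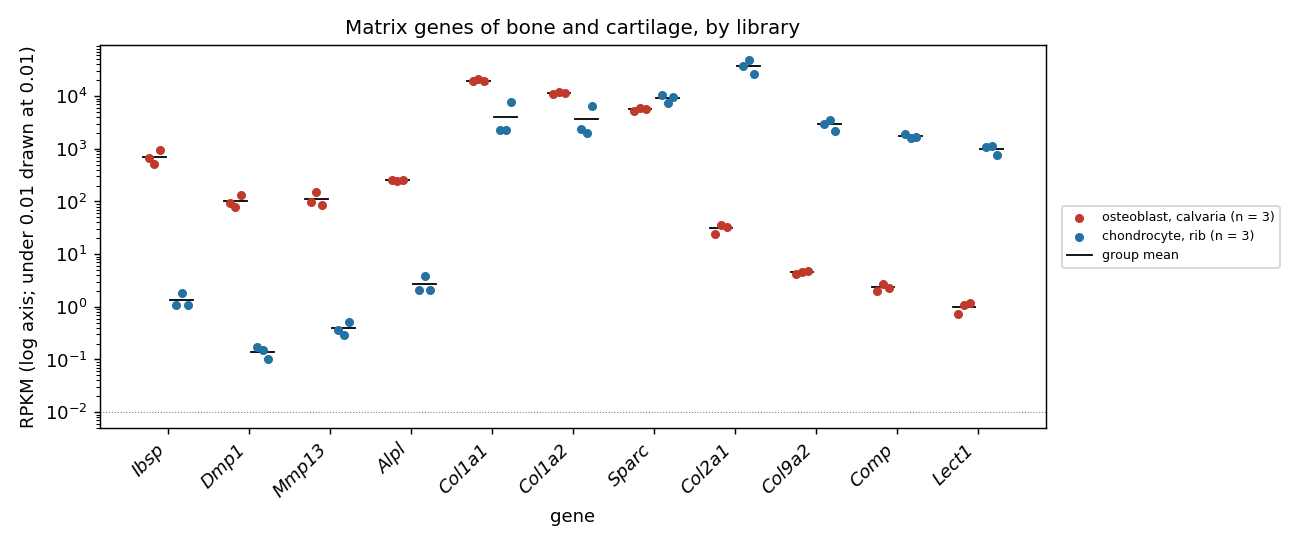
RPKM of 11 matrix genes (log axis) in each of the 3 osteoblast and 3 chondrocyte libraries, with group means as lines. Ibsp, Dmp1, Mmp13 and Alpl lie at least 94.5-fold apart between group means, Col1a1 4.81-fold apart, and Col2a1 1213-fold apart in the other direction. The chondrocyte mean of Col1a1 is raised by replicate 3 (7765 RPKM, against 2270 and 2259 in replicates 1 and 2).

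Cartilage transcription regulators moved with the matrix: 11 of 13 tested were higher in chondrocytes, Zfp219 was higher in osteoblasts (0.45) and Epas1 was not called, and the same numbers held adjusted over the list alone. The call of Zfp219 was lost when any one osteoblast library was left out and under median-of-ratios scaling. Sox9, the central activator of cartilage genes, stood at 143 ± 44.4 against 4.31 ± 1.61 RPKM (-4.76), and its partner Sox5 at 12.8 ± 1.28 against 0.825 ± 0.0296 RPKM (-2.92). The forkhead gene Foxa3, at 6.03 ± 1.11 RPKM, was nearly absent from osteoblasts at 0.0253 ± 0.00609 RPKM. Camera in limma gave a Benjamini-Hochberg adjusted p = 2.77e-10, and adjusted p = 0.166 with an estimated correlation. Across the Sox family, 5 of 8 tested genes were higher in chondrocytes (Sox9, Sox5, Sox8, Sox6 and Sox13), Sox4 and Sox12 were higher in osteoblasts and Sox11 was not called, also adjusted over the list alone. Camera gave the Sox list an adjusted p = 0.000926, and adjusted p = 0.166 with an estimated correlation.

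Enzymes that build sulfated proteoglycans, the charged sugars of cartilage, were mostly higher in chondrocytes, with 9 of 16, while 4 were higher in osteoblasts and 3 were not called, also adjusted over the list alone. Csgalnact1, which starts chondroitin sulfate chains, stood at 12.7 ± 4.97 against 0.378 ± 0.0630 RPKM (-3.25), and Papss2, which makes the sulfate donor, at 96.2 ± 30.2 against 14.3 ± 0.956 RPKM (-2.62). The 4 on the osteoblast side (Papss1, Chst12, Chpf and Xylt2) differed by 0.30 to 0.86. Only 1 was called there without osteoblast replicate 1 or 2, and under median-of-ratios scaling the list counted 1 higher in osteoblasts and 11 lower. Camera in limma gave a Benjamini-Hochberg adjusted p = 1.70e-05, and adjusted p = 0.188 with an estimated correlation.

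Genes known as markers of hypertrophic chondrocytes, the last stage of cartilage before bone replaces it, were largely higher in osteoblasts: 6 of 8, with Col10a1 higher in chondrocytes and Ihh not called, also adjusted over the list alone. The members that were higher, among them Mmp13 (6.30), Alpl (6.15), Panx3 (4.13) and Ibsp, are also known osteoblast genes. Col10a1, the collagen of the hypertrophic zone, varied among the chondrocyte libraries at 19.9, 58.4 and 3.32 RPKM, against 0.503 ± 0.491 in osteoblasts. Ihh was at 5.07 ± 1.17 and 3.16 ± 3.27 RPKM, and without chondrocyte replicate 2, where it reached 6.93 RPKM, it was called higher in osteoblasts (limma, Benjamini-Hochberg adjusted p = 0.000168). By camera, hypertrophic chondrocyte markers had an adjusted p = 0.0447, which was 0.0923 without chondrocyte replicate 3, and adjusted p = 0.514 with an estimated correlation.

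Positional genes differed between the skull and rib cells. Of 39 Hox genes, which mark position along the trunk, 11 were tested and all 11 were higher in rib chondrocytes, also adjusted over the list alone. Hox genes near 0 in osteoblasts pass the filter only where chondrocytes are high, so this count and the list test lean that way by selection. Without a filter on low values 20 of 31 were higher in chondrocytes and 0 in osteoblasts, with a median log2 difference of -0.37. Hoxc8 stood at 25.7 ± 5.58 against 0.0218 ± 0.00524 RPKM (-4.69), Hoxa5 at 25.6 ± 6.18 against 0.0185 ± 0.0198 RPKM (-4.68), and Hoxa6 (-3.67) was at the table's floor in every osteoblast library. Camera in limma gave a Benjamini-Hochberg adjusted p = 1.13e-14, and adjusted p = 0.188 with an estimated correlation. Among regulators of cranial patterning 9 of 12 were higher in calvarial osteoblasts, led by Alx4 (46.4 ± 3.20 against 0.566 ± 0.443 RPKM), Zic2 (18.5 against 0.0487 RPKM) and Twist1 (109 ± 17.1 against 8.26 ± 5.20 RPKM). Foxc1, Foxc2 and Alx1 were higher in chondrocytes, and the same 9 and 3 calls were counted adjusted over the list alone. By camera, cranial patterning regulators were not set apart (adjusted p = 0.293), though they were under median-of-ratios scaling (0.0249). Of trunk and rib regulators only 3 of 13 were tested: Tbx15 was higher in osteoblasts (9.97 against 0.123 RPKM) and Meox1 and Meox2 were not called, also adjusted over the list alone, though 2 of the list were higher in osteoblasts without chondrocyte replicate 3 (camera adjusted p = 0.635).

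**Figure D3:**
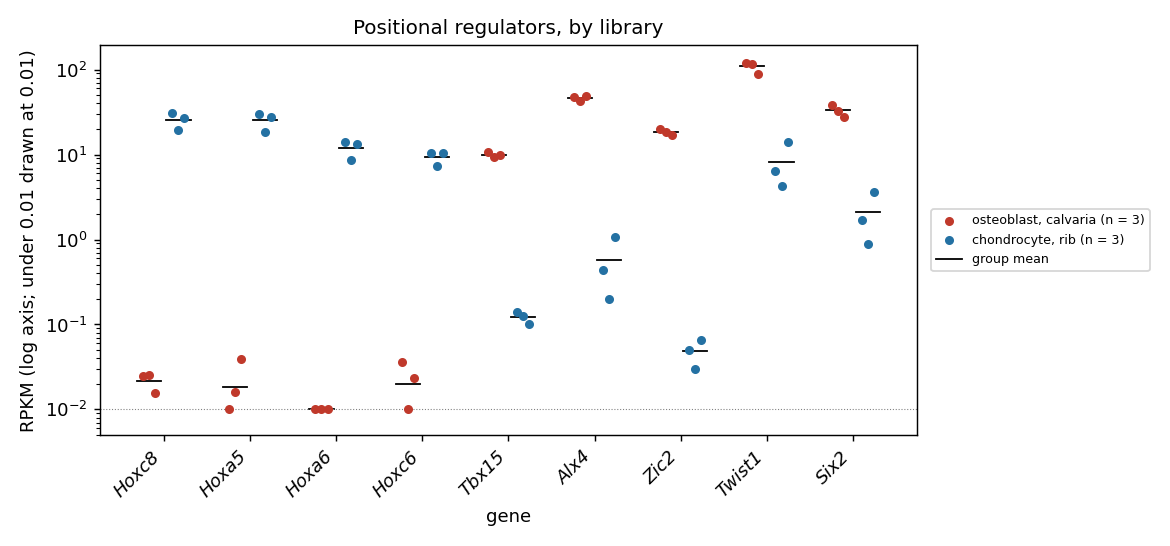
RPKM of 9 positional regulators (log axis; values under 0.01 drawn at 0.01) by library, with group means as lines. The 4 Hox genes lie higher in all 3 rib chondrocyte libraries, and Tbx15, Alx4, Zic2, Twist1 and Six2 lie higher in all 3 calvarial osteoblast libraries.

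Collagen genes were divided. Of 34 tested, 18 were higher in osteoblasts, 13 were higher in chondrocytes and 3 were not called (Col6a1, Col8a1 and Col23a1), also adjusted over the list alone. Under median-of-ratios scaling the counts were 10 and 13. The fibrillar Col1a1, Col1a2 and Col5a1 were on the osteoblast side with Col22a1 and Col26a1, and the cartilage Col2a1, Col9a1, Col9a2, Col9a3 and Col11a2 on the chondrocyte side. The list's median log2 difference was 0.86 and its mean -0.61. By camera, collagen genes lay on the chondrocyte side (limma, Benjamini-Hochberg adjusted p = 0.0234), with adjusted p = 0.504 with an estimated correlation, and the call ended without chondrocyte replicate 3 (0.0981) and under median-of-ratios scaling (0.813). Proteinases that cut matrix, the Mmp and Adamts families, were higher in osteoblasts for 19 of 25 tested, lower for Adamts3, Adamts6 and Mmp16, and not called for 3, also adjusted over the list alone. Mmp13, a collagenase, was at 111 ± 34.6 against 0.388 ± 0.119 RPKM, and Adamts14 and Adamts2, which trim procollagen, differed by 3.58 and 3.18. By camera, metalloproteinases had an adjusted p = 0.111, and 0.0280 without chondrocyte replicate 3.

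Signalling genes also differed in both directions. Of 23 tested Wnt pathway genes 14 were higher in osteoblasts, 4 were higher in chondrocytes (Sfrp1, Frzb, Sfrp5 and Lef1) and 5 were not called, also adjusted over the list alone. The ligand Wnt10b stood at 30.3 ± 1.32 against 0.179 ± 0.0320 RPKM (4.73), and the transcription factor Tcf7 was 33.9-fold higher (4.08). Wif1, a secreted Wnt antagonist, was not called, at 128 ± 17.9 RPKM in osteoblasts and 288, 54.6 and 261 RPKM in the chondrocyte libraries. Without chondrocyte replicate 2 its log2 difference was -1.10 (limma, Benjamini-Hochberg adjusted p = 0.000271). The Wnt list did not stand apart from other genes (camera adjusted p = 0.748). Of 16 FGF pathway genes 6 were higher in chondrocytes, 4 were higher in osteoblasts and 6 were not called, also adjusted over the list alone. Fgfr3, the receptor that restrains chondrocyte growth, stood at 89.4 ± 20.1 against 19.8 ± 1.35 RPKM, and the decoy receptor Fgfrl1 at 94.5 ± 7.58 against 11.6 ± 0.975 RPKM. By camera, FGF pathway genes lay on the chondrocyte side (adjusted p = 0.00335), a value that was 0.0555 under median-of-ratios scaling, and adjusted p = 0.166 with an estimated correlation.

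Of 23 BMP and GDF pathway genes 10 were higher in osteoblasts and 8 in chondrocytes, also adjusted over the list alone, and 6 and 10 under median-of-ratios scaling. Bmp8a (3.07) and the antagonist Nog (2.83) were on the osteoblast side, and Bmp5 (-3.51) and the joint factor Gdf5 (-2.51) on the chondrocyte side. The list's median was 0.20 and its mean 0.02. By camera, BMP and GDF pathway genes lay on the chondrocyte side (limma, Benjamini-Hochberg adjusted p = 0.0492), with adjusted p = 0.504 with an estimated correlation. That camera call ended without osteoblast replicate 1 or 2 (0.0619 and 0.0957) and without chondrocyte replicate 1 or 2 (0.0686 and 0.0625), and under median-of-ratios scaling (0.287). Of 11 hedgehog pathway genes 4 were higher in each cell type, also adjusted over the list alone, against 2 in osteoblasts and 6 in chondrocytes under median-of-ratios scaling. Gli1 and Hhip, targets of the pathway, were at 27.0 against 7.93 RPKM and 10.1 against 0.659 RPKM in favour of osteoblasts, Ptch1 and Sufu were also higher there, and Boc, Gas1, Gli2 and Gli3 were higher in chondrocytes. The hedgehog median was 0.12 and mean 0.18, with camera on the chondrocyte side (adjusted p = 0.111).

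Metabolic and proliferation genes completed the fixed lists. Of 21 glycolysis and hypoxia genes 9 were higher in osteoblasts and 5 in chondrocytes (Bnip3, Slc2a1, Hk2, Ndrg1 and Pdk1), also adjusted over the list alone, against 2 and 8 under median-of-ratios scaling. The glucose transporter gene Slc2a1 stood at 25.1 ± 8.85 RPKM in chondrocytes against 4.48 ± 0.497, while Vegfa, the angiogenic factor, was at 7.83 ± 2.53 against 19.6 ± 0.350 RPKM. The list's median was 0.34 and mean -0.05. By camera, glycolysis and hypoxia response genes lay on the chondrocyte side with an adjusted p = 0.111, and 0.0499 and 0.0317 without chondrocyte replicates 1 and 3. Of 19 cell cycle genes 16 were higher in osteoblasts, also adjusted over the list alone, and 6 under median-of-ratios scaling. With 1 library left out the count ran from 9, without osteoblast replicate 2 or chondrocyte replicate 3, to 19, without chondrocyte replicate 2. With all libraries Mki67, Cdk1 and Cenpf were not called. Rrm2 was 4.94-fold higher (2.11). Cdk1 was called without chondrocyte replicate 2 (adjusted p = 7.76e-05). The call of Ccna2 (limma, Benjamini-Hochberg adjusted p = 0.0185) ended without osteoblast replicate 2 (0.0566) or chondrocyte replicate 3 (0.0586). The chondrocyte libraries differed among themselves for these genes, with Ccna2 at 4.94 ± 5.29 RPKM. By camera, cell cycle genes had an adjusted p = 0.0821, and were called without chondrocyte replicate 2.

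Markers of other cells were read beside these results. Tendon, perichondrium and fibroblast genes were higher in osteoblasts for 8 of 13 and in chondrocytes for 3 (Col14a1, Kera and Tnmd), also adjusted over the list alone, and 4 each way under median-of-ratios scaling. Only 5 were higher in osteoblasts without osteoblast replicate 1 or 2 or chondrocyte replicate 1. The list's median was 0.66 and its mean 0.40, with camera on the chondrocyte side (adjusted p = 0.635). Col3a1 stood at 2445 ± 449 against 1016 ± 775 RPKM, a call (limma, Benjamini-Hochberg adjusted p = 0.0228) that ended without osteoblast replicate 1 or 2 (0.0701 and 0.0678) or chondrocyte replicate 1 or 2 (0.0731 and 0.0841). Dpt gave the largest called difference of the list, at 27.3 ± 13.7 against 0.200 ± 0.0726 RPKM (4.43), and passed the filter through the osteoblast libraries alone. Postn was at 676 ± 200 against 1303 ± 924 RPKM and not called. Among 4 erythroid genes Hba-a1 was called over all genes (1.37), though not without osteoblast replicate 2 (limma adjusted p = 0.0801) or 3 (0.0689), and none adjusted over the list alone, and the globin genes are near-identical copies. Of 16 muscle markers 2 were tested: Tnnt3 was at 20.8 ± 16.8 RPKM in chondrocytes (13.1, 40.1 and 9.16 in replicates 1 to 3) against 0.871 ± 0.156, Tnni2 differed by -1.19, and the other 14 did not pass the filter. Of 12 neural and glial markers only S100b (-3.39) and Tubb3 (2.99) were tested, 1 called each way, which does not show such cells in either group. Fabp4 (-2.07) was the adipocyte marker tested, and Egfl7 and Krt10 the endothelial and epidermal ones, neither called. These calls were the same adjusted over the list alone. Of 16 dissociation stress genes 6 were higher in osteoblasts and 3 in chondrocytes, 5 and 2 adjusted over the list alone, and 3 and 7 under median-of-ratios scaling. Without chondrocyte replicate 2 the counts were 4 and 2, and without osteoblast replicate 3 only 1 was higher in chondrocytes. Fos was at 726 ± 128 against 304 ± 60.8 RPKM, and Ier3, the largest called difference, at 67.5 ± 12.4 against 13.6 ± 5.61 RPKM (2.30). The list had median 0.38, mean 0.38 and a camera direction toward chondrocytes (adjusted p = 0.243). None of 5 sex-linked transcripts was called over all genes or adjusted over the list alone (limma), but 2 were lower in osteoblasts under median-of-ratios scaling and 3 after quantile normalization. Xist was called lower in osteoblasts without osteoblast replicate 1 (adjusted p = 0.0182) or chondrocyte replicate 3 (0.0245). Ribosomal protein genes were higher in osteoblasts for 68 of 78, or 72 adjusted over the list alone, but 10 were higher and 2 lower under median-of-ratios scaling. Rps12 was at 1256 ± 56.4 against 742 ± 90.0 RPKM. By camera, ribosomal protein genes lay on the osteoblast side (adjusted p = 0.00279), a value that was 0.243 under median-of-ratios scaling, and adjusted p = 0.734 with an estimated correlation.

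**Figure D4:**
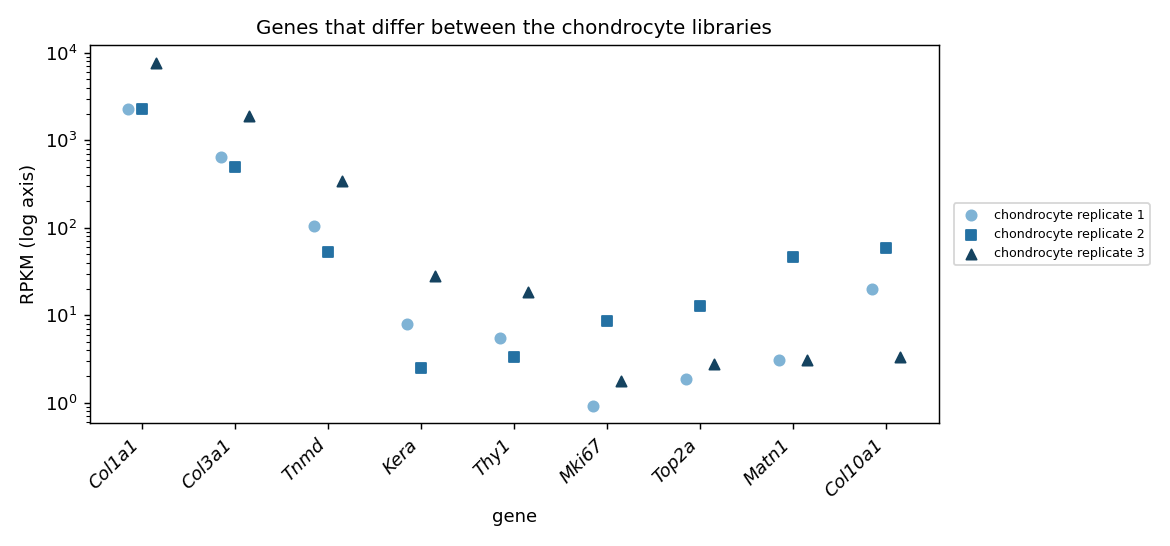
RPKM of 9 genes (log axis) in chondrocyte replicates 1, 2 and 3, one point per library, genes chosen after values were seen. Col1a1 was 3.43-fold higher in replicate 3 than in the mean of the other 2, and Mki67 stood at 8.49 RPKM in replicate 2 against 0.911 and 1.76.

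In all, 6224 genes were higher in osteoblasts and 1512 were higher in chondrocytes, and 3482 of the 11218 tested were not called. At least 2-fold, the counts were 2185 and 600. On RPKM as deposited the groups did not overlap for 8484 genes, or 75.6%. Chance gives 10% for a single gene, but genes move together and a library's scale moves them all, so that 10% does not test this share. The median log2 difference of all tested genes was 0.43 toward osteoblasts, and the counts of calls depended on how libraries were scaled. Osteoblast calls made up 80.5% of all calls on RPKM as deposited, 72.9% with equal RPKM totals (5396 and 2010 genes), 56.5% with equal totals outside the 50 most abundant genes (3904 and 3009), 51.0% after quantile normalization (3597 and 3456) and 49.6% under median-of-ratios scaling (3415 and 3470). Of the 28 lists tested, 14 were called by camera and none with an estimated correlation, while fry, which tests each list without reference to other genes, called 22. The loss of the 14 calls does not rest on correlation alone. Osteoblast transcription regulators and FGF pathway genes had estimated correlations of -0.0648 and -0.00700, below the preset 0.01, and lost their calls too. Even cartilage matrix reached only a camera adjusted p of 0.166 that way. A list missed by that version is therefore not shown to lie level with other genes.

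**Figure D5:**
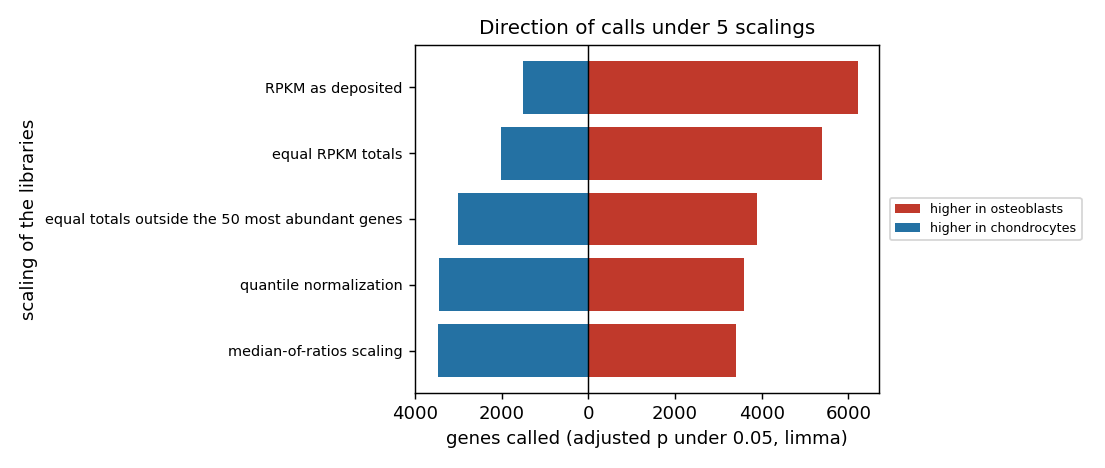
Number of genes called by limma as higher in osteoblasts (right) and higher in chondrocytes (left) under 5 scalings of the same 6 libraries. The counts run from 6224 and 1512 on RPKM as deposited to 3415 and 3470 under median-of-ratios scaling.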

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

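The tests of transcripts as deposited, of reads worked back from RPKM and of transcript shares were chosen after seeing the data. Genes higher in osteoblasts and in chondrocytes numbered 3415 and 3470 under median-of-ratios scaling, 3597 and 3456 after quantile normalization and 3904 and 3009 with equal totals outside the 50 most abundant genes. For genes at least 2-fold higher in osteoblasts and genes at least 2-fold higher in chondrocytes these were 1106 and 992, then 1085 and 1003, and 1233 in osteoblasts for the last. A filter of mean RPKM of at least 5, which tests fewer genes, gave 4092 and 885, and 1367 and 397 at least 2-fold. A pseudocount of 5 left 900 and 347 genes at least 2-fold apart, and limma treat 865 and 334. Gene lists called fell to 0 with an estimated correlation and numbered 22 by fry, which reversed the direction of the Sp genes (adjusted p = 0.000299). Among named genes Sp3 reversed to -0.20, -0.15 and -0.12 under median-of-ratios, quantile and outside-the-top scaling, Fgfr1 to -0.39 and -0.30 under the first and last of these, and Smo to -0.38 under median-of-ratios. Median-of-ratios and outside-the-top scaling apply 1 factor per library, which lowers the log2 differences together (median of all genes 0.43, then 0.00927 and 0.0854), so small positive values turn by construction. Krt10 reversed to -0.38 after quantile normalization. For the quantile reversals and the other changes the cause was not tested. With the replicate number as a block, 5892 and 1376 genes were called, and 2188 and 598 at least 2-fold. Deviations of same-numbered libraries correlated at 0.0791, 0.00964 and -0.155, and those of other pairs across the groups at -0.150 to 0.126. No pairing by number was seen, though such values cannot show how the samples were collected. Leaving out each library gave 5300 to 6319 and 1206 to 1898 genes, 1958 to 2436 and 575 to 621 at least 2-fold, 13 to 15 lists, and an Sp7 log2 fold change of 5.50 to 5.90. Over all alternatives Sp7 stayed between 4.27 and 6.37. Transcripts tested as deposited gave 6871 and 1729 calls among 13162. Voom on 8236 genes with 1 transcript called 5700 against 5710, of which 5644 were shared in the same direction and 0 in opposite directions. Its reads came from the same RPKM and depths, so the shared direction was built in and the scaling was not tested. Transcripts with a changed share numbered 345 to 383 over the floors and moderations tried, and 207 to 293 with a library left out, lowest without osteoblast replicates 1 and 2 (207 and 224) and chondrocyte replicate 1 (218). At 1 RPKM an estimated 54.1 to 71.9 reads of a 2 kb transcript stand behind a value, and whether depth limits calls there was not tested.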

Other observations

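Apart from the splits of the libraries for lists and for transcript shares, all tests in this part were chosen after the result was seen. Several genes used different transcripts in the 2 cell types, by the authors' estimates of each transcript. Among 3051 transcripts of 1258 genes, 382 transcripts of 210 genes differed in their share of the gene (limma on log2 odds, Benjamini-Hochberg). With a library left out 207 to 293 transcripts were called. In 36 genes all libraries of one cell type had a main transcript other than that of the other. Postn, the gene of the matrix protein periostin, was the largest case: NM_001198766 made up 61.9% ± 1.86 of its RPKM in osteoblasts and 0.130% ± 0.0221 in chondrocytes (SD, n = 3 each, limma adjusted p = 9.06e-06). In GENCODE M21 that transcript lacks both an 81-nucleotide exon of NM_001198765 and an 84-nucleotide exon of NM_015784, of which NM_001198765 made up 54.9% in chondrocytes. Plod2, whose enzyme hydroxylates lysines of collagen, had 94.4% ± 1.04 of its RPKM in NM_001142916, the form with an extra 63-nucleotide exon, in osteoblasts and 55.6% ± 3.35 in chondrocytes (limma adjusted p = 0.000479). Col2a1 NM_031163, which holds a 204-nucleotide exon that NM_001113515 lacks, was 45.8% ± 1.07 in chondrocytes and 6.64% ± 2.58 in osteoblasts, where the gene was low. Xbp1 NM_001271730 was 4.43% ± 0.407 in osteoblasts and 30.0% ± 2.02 in chondrocytes, while the gene's total did not differ by the test (59.4 against 57.8 RPKM). The real split called 382 transcripts and the highest of the other splits 0, so 1 of 10 splits reached the real value, and 10 are too few for a share under 0.05.

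The chondrocyte libraries differed from one another in proliferation and cartilage genes. Replicate 2 held more of the mitotic genes Mki67 (8.49 RPKM, against 0.911 and 1.76 in replicates 1 and 3) and Top2a (12.8, against 1.87 and 2.75), and of the cartilage gene Matn1 (46.6, against 3.12 and 3.10). Its Pcna was 31.4 RPKM, against 32.5 and 37.8. Xist and the Y-linked Ddx3y were both present in each of the 6 libraries, Xist at 9.55 to 22.0 RPKM and Ddx3y at 3.79 to 8.97 RPKM. Zfp648 was at 18.4 RPKM in chondrocytes and at the floor of the table in all 3 osteoblast libraries.

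Type I collagen in chondrocyte replicate 3 was 3.43-fold above the mean of replicates 1 and 2 (Col1a1 7765 RPKM, against 2270 and 2259). Sp7-positive osteoblasts in the rib preparation are argued against as its source: Col1a1 reached 39.4% of its osteoblast level there, while 9 osteoblast-restricted genes, Sp7, Ibsp and Alpl among them, had a median of 0.652% (range 0.0955% to 2.48%). Across all tested genes, though, replicate 3 lay nearer the osteoblast libraries (r of 0.817 to 0.820) than replicates 1 and 2 did (0.777 to 0.780). These 9 genes do not account for that. Scaling of the whole library is argued against by a median log2 ratio of 0.10 over all tested genes. Tendon, perichondrium or fibroblast cells may be a source, since 11 of 12 markers fixed beforehand were highest in replicate 3. Chance gives 4 for independent genes, but these move together (estimated correlation 0.742 for the list), so they are not 12 separate draws. Tnmd was at 341, Col14a1 at 271 and Dcn at 345 RPKM there. Of these 12 markers 7 were higher in the sorted osteoblasts, so they are not specific to such cells. No sort was recorded for the rib cells, and apart from these cell sources no biological explanation was tested.

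Most called genes were higher in osteoblasts, at 80.5% of calls. The 50 most abundant genes held 38.2% ± 3.12 of chondrocyte RPKM and 27.3% ± 0.574 of osteoblast RPKM (SD, n = 3 each). Whether this larger share accounts for the excess stays open: equal totals outside the 50 most abundant genes gave a median log2 difference of 0.0854, but such scaling nearly centres the other genes whatever the cause, and a true difference between the cell types is as open, as RPKM carries no absolute scale. Transcript length as the whole cause cannot be judged either. Over 10 length classes the median fell from 0.70 in the shortest to 0.21 in the longest (95% interval over resampled genes 0.17 to 0.25). It stayed above 0 in all 10, but where 0 lies depends on the scaling. The median of all tested genes was 0.43 as deposited and 0.00927 under median-of-ratios scaling. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 reached the real 7736 genes and 1 the real 2785 at least 2-fold (highest other 0 for each), and 2 reached the real 14 lists, the highest other giving 14 with osteoblast replicates 1 and 2 set beside chondrocyte replicate 1.

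Among 4 gene families picked because they stood out, nuclear-encoded respiratory chain genes had a median log2 difference of 1.06, against 0.53 to 0.76 in the central 95% of 10000 matched random lists, and zinc finger Zfp genes -0.0257 against 0.31 to 0.52. The gap to genes of the same length and expression class was 0.42 for respiratory chain genes (0.36 to 0.44 with a library left out) and -0.43 for Zfp genes (-0.46 to -0.39). The class of length and level therefore does not account for the gaps, but length within a class was not tested. The 4 families had estimated correlations of 0.25 to 0.53, which random lists need not share, so the 95% ranges may be too narrow for them. Proteasome subunit genes (median 0.94 against 0.37 to 0.78, 35 of 36 higher in osteoblasts) and mitochondrial ribosomal protein genes (0.81 against 0.47 to 0.74, 68 of 76) also lay above their matched lists, so the rise was not particular to the respiratory chain. None of the 4 stood apart by camera with an estimated correlation (limma, Benjamini-Hochberg adjusted p = 0.309 for each, and 3.26e-08 to 5.01e-06 with the preset one), a version that also called none of the 28 fixed lists. The glycolysis list fixed beforehand had a median of 0.34, below the 0.43 of all genes, so no general rise of energy genes is shown. Of 79 respiratory chain genes 74 were called higher in osteoblasts (57 under median-of-ratios scaling, with 2 lower, against 30 and 1 for proteasome and 46 and 6 for mitochondrial ribosomal genes), and of 224 Zfp genes 54 were higher and 62 lower (14 and 123), with cell type, sort, digestion and site all untested as sources.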
